A study of Homo sapiens with 3 samples.

How the data were processed

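RNA-seq was carried out on 3 libraries of cells enriched for circulating tumor cells from patients with melanoma. Per the labels' protocols, total RNA was extracted with TRI Reagent and libraries were made with the Illumina TruSeq RNA Access kit, which captures coding exons with probes, and per the series' design text they were sequenced on an Illumina HiSeq instrument. The capture step favours exons of coding genes, so noncoding RNA levels depend on the probes. The deposited values are raw counts of reads per gene, 1 value for each of 57820 Ensembl gene identifiers and library, whole numbers whose totals differ between libraries, with no normalization. Per the submitters' processing notes, CASAVA 1.8 and STAR 2.4.2a were used; the genome build, the annotation and the strand setting of the counting are not given in the sources used here, and no coordinates are printed for that reason. The design had foreseen read categories for unassigned reads and separate strand columns; these were not analysed here, and the single count column per library was used. Gene-assigned reads numbered 44319536, 47718579 and 32454638.

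Symbols were found for 51996 identifiers in a table of gene names, and 52338 were present in GENCODE 29, which gave gene type, exon length and the GC content of the longest transcript; identifiers outside it held at most 0.644% of a library's reads. Counts were scaled to CPM with edgeR 4.0.16 TMM factors (0.903, 1.02 and 1.08) in R 4.3.3, and log2 CPM used a prior count of 2. Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Intervals of shares are 95% Wilson intervals. PCR reads without molecular identifiers are not independent molecules, so intervals and the limit of 3 reads for a count of 0 cover counting error only.

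Before the data were examined, 28 gene lists, the tests and the rule for named genes were fixed. Of 470 list entries 465 matched an identifier; BAGE, PECAM1, GIF, CCL3 and CCL4 did not. A list's level was the median log2 CPM of all matched members. Named genes were the 10 with the highest mean CPM, up to 3 highest members of each list, up to 6 of the melanocyte, cancer-testis and checkpoint lists with their members at 0 reads, and the 15 with the largest SD of log2 CPM among genes with a mean of at least 10 CPM. Genes on chromosome Y, 2 transcripts of X inactivation, genes whose level is set by common inherited variants, and immunoglobulin and T cell receptor genes were left out of the first and last of these. A few genes that the rule takes are not reported here. With 1 group there was no test between groups.

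The melanocyte list was compared with 59 background genes in each library by the difference of medians and an exact two-sided sign-flip permutation test. The spread of a list was the median SD of log2 CPM over members with a mean of at least 1 CPM, set against 10000 random lists matched in 20 expression bins, for 24 lists with at least 3 such members; limits were percentiles 2.5 and 97.5, with Benjamini-Hochberg adjustment. A chi-square test of homogeneity was run on genes with an expected count of at least 10 in every library. Both were tested on simulated data. The chi-square test on 12935 genes recovered 44.0%, 76.0%, 92.0% and 100.0% of genes changed by 1.2, 1.5, 2 and 4-fold, with 12 unchanged genes called. The list spread, on 12952 genes, placed 8.0% of unshifted lists outside the limits and 30.0%, 75.0% and 100.0% of lists shifted by 0.5, 1 and 2 log2 in 1 library above the upper limit. For the chi-square test the simulated counts held counting error only (Poisson), so its rates do not cover other variation between libraries. For the list spread the simulated genes varied independently with a common dispersion, in random lists of equal size. Members of the real lists can vary together, so these rates need not hold for them.

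Alternatives fixed beforehand were DESeq2 1.42.0 size factors, no factor, a prior count of 0.5, other count filters, CPM per kilobase of exon, the mean in place of the median, and leaving out each library. Added after the data were seen were a floor of 3 reads, leaving out members at 0 reads in every library, leaving out MITF, SERPINA1, TG, VIL1 and ZP3, leaving out each library for the named genes, and removing the trend of each library on GC content and transcript length. That trend was a polynomial of degree 4 in the rank of each property with 2 cross terms, fitted over 10697 genes (98.6% of those with a mean of at least 1 CPM), in this 1 form.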

Results

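RNA of blood cell preparations enriched for circulating tumor cells was sequenced in 3 libraries from patients with melanoma, and these libraries form the 1 group that the labels define. Circulating tumor cells are cells that a tumor sheds into the blood, where they are rare among leukocytes. The series title places the work in patients given combined immunotherapy; how the cells were enriched, and when blood was drawn relative to treatment, is not given in the sources used here. The libraries held 44319536, 47718579 and 32454638 gene-assigned reads (libraries 1, 2 and 3). At least 10 reads were counted for 13136, 13498 and 12936 genes, and 12184 genes reached that number in every library, of which 10985 were protein-coding. A gene at 0 reads could have had up to 3 reads by chance, which corresponds to 0.0750, 0.0616 and 0.0853 CPM (reads of a gene scaled to a common library size) in libraries 1, 2 and 3; such limits and all binomial intervals cover counting error only. Levels below are CPM as mean ± SD over the 3 libraries (n = 3), and the level of a gene list is the median log2 CPM of its members. The labels do not say whether the 3 libraries came from 3 donors, so an SD describes the spread between these samples. No blood sample without tumor cells was analysed here, and genes of tissues outside blood and skin served as the background.

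The genes with the highest CPM, not corrected for transcript length, included 2 noncoding RNAs and 2 monocyte genes. Their order is one of reads and not of transcript molecules. The long noncoding RNA MALAT1 was first at 22843 ± 4069 CPM, followed by AHNAK, which encodes a large scaffold protein, at 12552 ± 2029.7 CPM. The small nucleolar RNA SNORA73B stood at 12376 ± 9319 CPM, with 3.49-fold between its highest and lowest library and a mean of 7000 CPM without library 1. FTH1, a subunit of the iron store ferritin, was at 11688 ± 3067 CPM, ACTB at 10324 ± 4194 CPM, and PSAP, the precursor of lysosomal saposins, at 10175 ± 2726 CPM. The monocyte genes LYZ (lysozyme) and VCAN (versican) reached 9061 ± 1650 and 7587 ± 2350 CPM. B2M, the light chain of class I antigen-presenting molecules, was at 8923 ± 3066 CPM and NAMPT, an enzyme of NAD synthesis, at 8450 ± 1134 CPM. The 10 highest genes of each library took 12.7% (95% Wilson interval 12.6 to 12.7), 10.7% (10.7 to 10.7) and 10.9% (10.9 to 10.9) of its reads. Protein-coding genes took 92.2% (92.2 to 92.2), 93.9% (93.9 to 93.9) and 92.3% (92.3 to 92.3).

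Genes of neutrophils and monocytes led the cell type lists. All 15 neutrophil genes had at least 10 reads in every library and a median of 8.65 ± 0.66 log2 CPM, against 8.22 ± 0.20 for 16 ubiquitous reference genes such as ACTB and EEF1A1 (2940 ± 67.3 CPM). The neutrophil median was above the reference median in libraries 1 and 2 and below it in library 3 (7.98 against 8.38 log2 CPM). CSF3R, the receptor of the neutrophil growth factor G-CSF, was at 2435 ± 855 CPM, the calcium-binding protein gene S100A8 at 1182 ± 377 CPM and the formyl peptide receptor gene FPR1 at 1165 ± 226 CPM. Whether neutrophils or other leukocytes gave the reads of these genes was not tested. All 12 monocyte genes were measured in every library (median 6.83 ± 0.32 log2 CPM), with FCN1 at 1963 ± 377 CPM after LYZ and VCAN. Of the 27 lists other than the background, 18 had a median of at least 1 CPM in every library. Levels are not corrected for transcript length, so the order of 2 lists carries the lengths of their members.

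Genes of other blood cells were present at lower levels. Eosinophil and basophil genes had a median of 3.15 ± 0.37 log2 CPM, with CLC at 179 ± 61.6 CPM, the histamine-forming enzyme gene HDC at 93.2 ± 50.1 CPM and MS4A2 at 14.8 ± 9.82 CPM. Platelet and megakaryocyte genes stood at 2.92 ± 0.10 log2 CPM, led by the chemokine gene PPBP (379.7 ± 82.9 CPM), TUBB1 (202 ± 36.4 CPM) and F13A1 (200.1 ± 42.5 CPM), which monocytes also express. The T cell list had a median of 2.11 ± 0.74 log2 CPM and 15 of its 16 members had at least 10 reads in every library. CD4, which monocytes also carry, was at 51.9 ± 16 CPM, and the T cell receptor complex genes CD3E and CD3D were at 20.8 ± 12.3 and 12 ± 5.4 CPM. Dendritic cell genes (2.06 ± 0.56 log2 CPM) were led by FCER1A at 54.8 ± 36.8 CPM, TCF4 at 24.4 ± 7.76 CPM and CLEC10A at 12.4 ± 9.83 CPM. Whether dendritic cells or other blood cells gave the reads of these genes was not tested. Cytotoxic and NK cell genes (1.16 ± 0.62 log2 CPM) included GNLY at 25 ± 8.6 CPM, GZMB at 8.01 ± 5.71 CPM and PRF1 at 7.69 ± 0.850 CPM. Without library 3, CD3E was at 13.7 CPM, FCER1A at 33.6 CPM, CLEC10A at 6.90 CPM, GZMB at 4.73 CPM and MS4A2 at 9.30 CPM.

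Granule genes that immature neutrophils transcribe had a median of 1.32 ± 1.11 log2 CPM, with BPI at 21.9 ± 12.2 CPM, LTF at 14.7 ± 8.91 CPM (9.64 without library 2) and CAMP at 11.9 ± 6.04 CPM. B cell genes were close to 1 CPM (0.17 ± 0.13 log2 CPM), with CD79B at 8.49 ± 1.5 CPM, BANK1 at 6.42 ± 4.43 CPM (3.88 without library 3) and CD22 at 1.83 ± 0.471 CPM. Plasma cell genes had a median of −3.14 ± 0.31 log2 CPM and 2 of 7 members with at least 10 reads in every library, XBP1 (19.0 ± 3.93 CPM) and JCHAIN (15.2 ± 7.69 CPM), while MZB1 was at 0.271 ± 0.188 CPM (0.165 without library 3). Erythroid genes stood at −1.36 ± 0.32 log2 CPM, although HBB reached 745 ± 178 CPM. HBA2 was at 129.6 ± 53.8 CPM, a value that its near-identical copy makes uncertain.

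**Figure D1:**
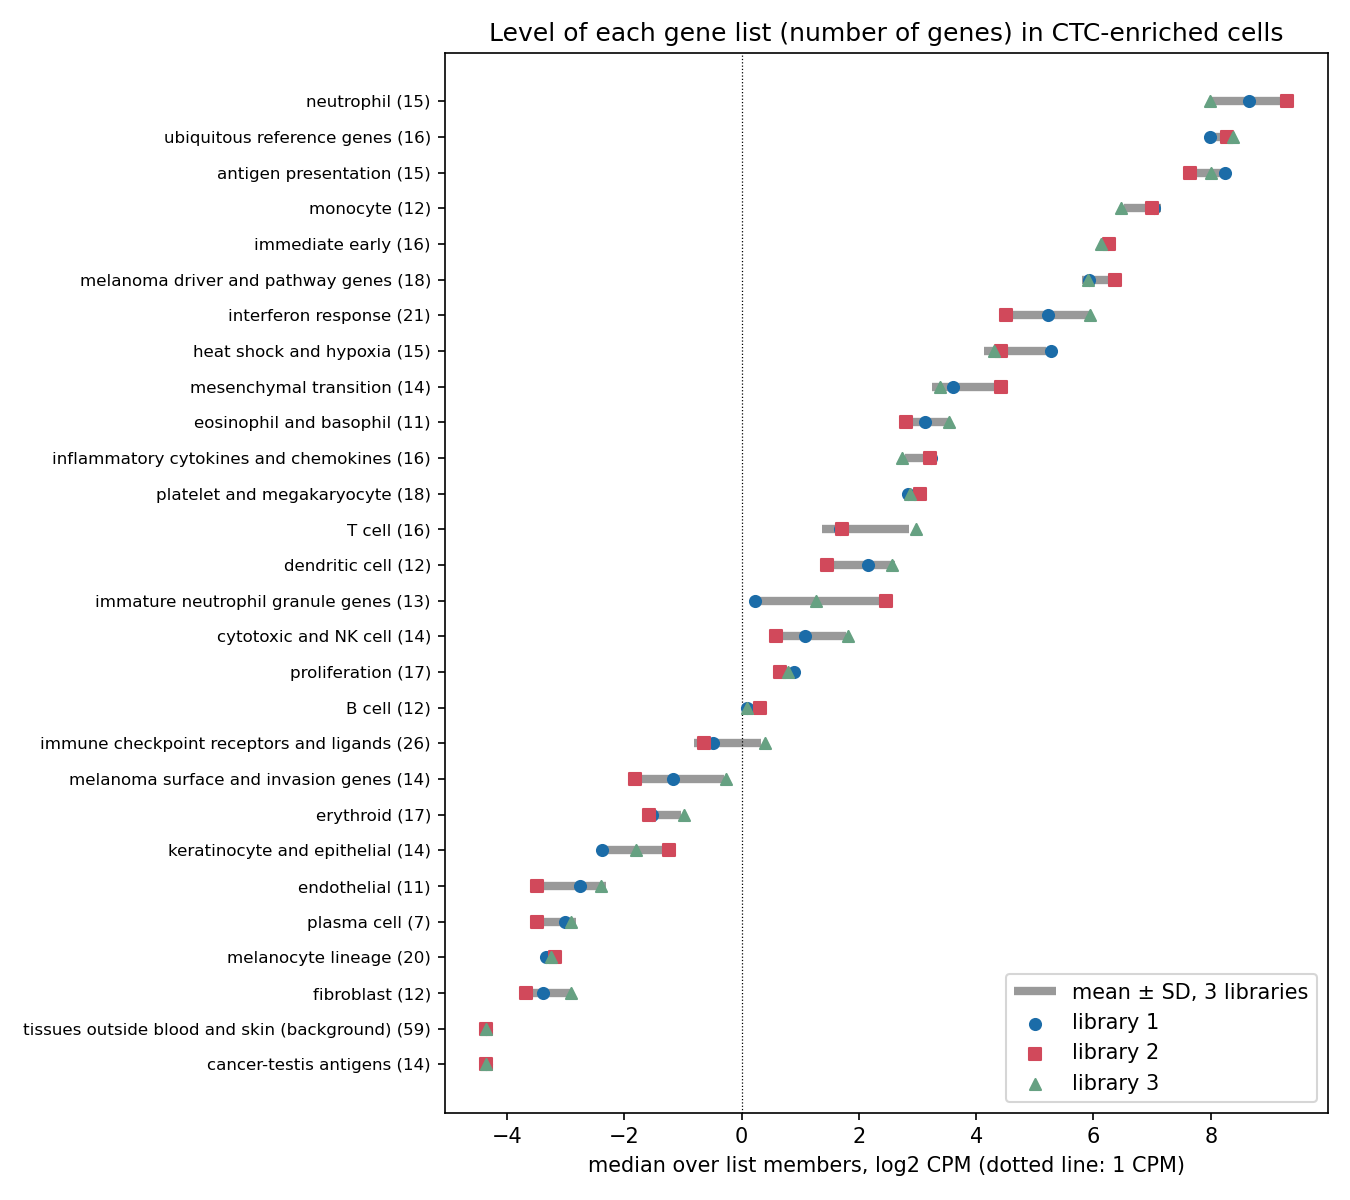
Median log2 CPM of each of the 28 gene lists in each library (symbols), with the mean ± SD over the 3 libraries as a bar; the dotted line marks 1 CPM and the number of genes per list is in parentheses. Neutrophil genes had the highest mean, 8.65 ± 0.66 log2 CPM, although the reference and antigen presentation lists lay above them in library 3, and the cancer-testis and background lists lay at −4.37, the value of a gene with 0 reads.

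Genes of the melanocyte lineage, the marker set for melanoma cells, were close to the limit of detection. Of 20 such genes, MITF and PMEL had at least 10 reads in every library and 4 genes (TYRP1, SOX10, MIA and CDH19) had 0 reads in every library. MITF (ENSG00000187098), a transcription factor of melanocytes that macrophages and mast cells also express, was at 7.19 ± 1.90 CPM and gave 206, 434 and 265 reads. The other 19 genes together gave 84, 93 and 92 reads in libraries 1, 2 and 3. PMEL (ENSG00000185664), a structural protein of the pigment organelle, gave 23, 15 and 10 reads (0.389 ± 0.161 CPM). RAB38 was at 0.429 ± 0.349 CPM, EDNRB at 0.252 ± 0.128 CPM, S100B at 0.213 ± 0.234 CPM and SLC45A2 at 0.210 ± 0.145 CPM. Of these, RAB38 and S100B fell to 0.232 and 0.0785 CPM without library 3, and SLC45A2 to 0.130 CPM without library 2. Which cells gave the reads of these genes was not tested. Of the pigment genes singled out after their values were seen, MLANA gave 2, 4 and 1 reads, TYR 2, 3 and 1 reads, and DCT 13, 2 and 9 reads.

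The background list was set beside these genes in the same libraries. At least 3 reads were counted for 7, 11 and 8 of the 20 melanocyte genes, or 35.0%, 55.0% and 40.0%, against 10, 15 and 8 of 59 background genes, or 16.9%, 25.4% and 13.6%. Of the background genes 31 had 0 reads in every library. SERPINA1, which monocytes and neutrophils also express, was at 1959 ± 318 CPM, TG at 26.6 ± 3.15 CPM and ZP3 at 1.90 ± 0.739 CPM; VIL1 and COL10A1 were the other background genes with at least 10 reads in every library. TG contains the leukocyte gene SLA (147 ± 94.1 CPM) on its opposite strand, and whether the counting used strand is not given in the sources used here. The median of the melanocyte list was 1.11 ± 0.08 log2 above that of the background list (higher in 3 of 3 libraries, exact two-sided sign-flip permutation p = 0.25, the smallest that 3 libraries allow). The background median lay at the value of a gene with 0 reads, so no list could lie below it. The direction and this p were therefore fixed once the melanocyte median was above 0 reads, and no conclusion is drawn from them. The difference from the background median was 1.05 ± 0.39 log2 for fibroblast, 1.23 ± 0.31 for plasma cell and 1.49 ± 0.56 for endothelial genes. It was 2.56 ± 0.57 log2 for keratinocyte and epithelial genes and 0.00 for cancer-testis antigens. An offset of this size was therefore not particular to melanocyte genes. The median background gene had 0 reads in every library, so the size of the melanocyte difference follows the prior count (2.49 log2 with a prior count of 0.5). That difference was 0.60 log2 with the mean of each list and 0.40 log2 per kilobase of exon. It was 0.00 when members under 3 reads were set to 3 reads and −2.10 when only members with 10 reads in some library were kept. The difference is therefore not read as a fold.

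**Figure D2:**
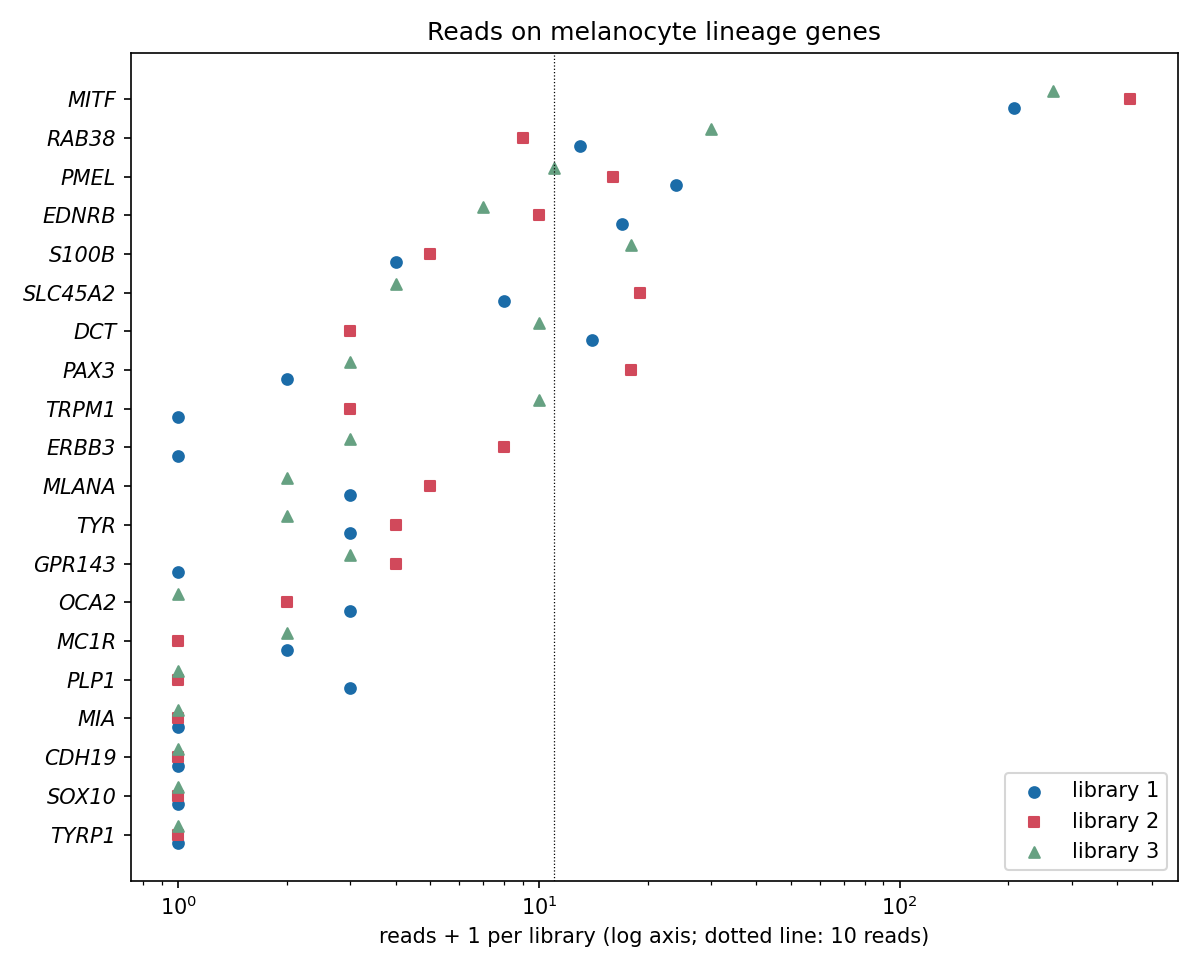
Reads plus 1 on a log axis for each of the 20 melanocyte lineage genes in the 3 libraries (symbols); the dotted line marks 10 reads. MITF lies between 206 and 434 reads, and 4 genes have 0 reads in every library.

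Cancer-testis antigens, which many melanomas express and healthy blood cells do not, were at 0 reads in every library for 12 of 14 genes, among them MAGEA1, MAGEA3, MAGEA4 and MAGEA6. MAGEC1 gave 7 reads in 1 library and PRAME 1 read in another. Several of these genes have near-identical copies, whose reads the counting could have left out.

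Melanoma surface and invasion genes had a median of −1.09 ± 0.78 log2 CPM, and 6 of 14 had at least 10 reads in every library. The highest were the death receptor gene TNFRSF10B at 240.0 ± 33.2 CPM, the growth factor receptor gene IGF1R at 177 ± 35.1 CPM and CHI3L1, which neutrophils and macrophages also express, at 117 ± 38.4 CPM. For none of these genes was it tested which cells gave the reads, so they are not read as a sign of melanoma cells. Melanoma driver and pathway genes, most of which are expressed in many cell types, had a median of 6.07 ± 0.26 log2 CPM. MAP2K1 was at 167 ± 15.8 CPM and BRAF at 166 ± 26.1 CPM.

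Genes of other solid tissues were mostly low. The fibroblast list had a median of −3.32 ± 0.39 log2 CPM, with COL1A1 at 1.94 ± 2.15 CPM (0.705 without library 1), COL6A3 at 1.38 ± 1.15 CPM (0.753 without library 1) and PDGFRB at 0.336 ± 0.0847 CPM. The endothelial list had a median of −2.88 ± 0.56 log2 CPM, with VWF, which platelets also hold, at 12 ± 5.0 CPM, ESAM at 2.51 ± 0.850 CPM and TEK at 1.46 ± 0.554 CPM. Keratinocyte and epithelial genes stood at −1.81 ± 0.57 log2 CPM, with KRT10 at 4.99 ± 3.94 CPM, KRT5 at 2.67 ± 2.4 CPM and CDH1 at 1.31 ± 1.33 CPM, the last 2 at 1.30 and 0.539 CPM without library 3. Mesenchymal transition genes stood at 3.80 ± 0.55 log2 CPM, and at 6.31 log2 CPM without members at 0 reads in every library. The highest members were VIM at 4229 ± 996 CPM, ZEB2 at 749 ± 143 CPM and TGFBI at 385 ± 99.7 CPM, which leukocytes also express.

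Among immune checkpoint receptors and ligands, the targets of immunotherapy antibodies and their partners, SIRPA and LGALS9 were highest. The list had a median of −0.24 ± 0.56 log2 CPM and 15 of 26 members with at least 10 reads in every library. SIRPA, the receptor of the "do not eat me" signal CD47, was at 284 ± 90.3 CPM and CD47 itself at 75.1 ± 19.0 CPM. LGALS9 was at 282 ± 95.5 CPM, VSIR (VISTA) at 135 ± 66.1 CPM, the costimulatory ligand gene CD86 at 57.3 ± 10.9 CPM and HAVCR2 (TIM-3) at 14.0 ± 1.02 CPM. VTCN1 had 0 reads in every library. Some approved drug targets were singled out after their values were seen, and other members such as LAG3 are not given here. CD274 (PD-L1) was at 6.72 ± 3.64 CPM, CTLA4 at 0.759 ± 0.361 CPM, and PDCD1 (PD-1) gave 5, 2 and 1 reads.

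Antigen presentation genes had a median of 7.97 ± 0.30 log2 CPM, led by B2M, CTSS (2950 ± 136 CPM) and CD74 (1131 ± 123 CPM); TAP2 was at 0 reads in every library. Immediate early genes stood at 6.21 ± 0.07 log2 CPM, with FOS at 3655 ± 1338 CPM, KLF6 at 1280 ± 487 CPM and DUSP1 at 972 ± 149 CPM. Inflammatory genes had a median of 3.06 ± 0.27 log2 CPM, but NFKBIA reached 5985 ± 1900 CPM, CXCL8 1398 ± 614 CPM and TNFAIP3 663 ± 167 CPM. Heat shock and hypoxia genes stood at 4.67 ± 0.53 log2 CPM, with HSP90AA1 at 851 ± 208 CPM, HSPA8 at 358 ± 133 CPM and VEGFA at 162 ± 44.9 CPM. Proliferation genes were at 0.77 ± 0.12 log2 CPM, with MKI67 at 24.3 ± 8.79 CPM, MCM5 at 15.5 ± 7.96 CPM and TOP2A at 5.98 ± 0.640 CPM.

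Interferon response genes, whose median was 5.22 ± 0.71 log2 CPM, had the spread between libraries that lay furthest above random lists, although the median SD of 4 keratinocyte and epithelial genes was larger (1.30 against 1.14 log2). Of its 19 members with a mean of at least 1 CPM, 17 were lowest in library 2, under each of the 3 scalings tried, and 17 differed by over 2-fold. The antiviral genes IFIT1 (ENSG00000185745) and RSAD2 were at 15.6, 3.30 and 52.8 CPM and at 20.9, 3.26 and 46.6 CPM in libraries 1, 2 and 3. GBP5, a guanylate-binding protein gene, was at 649, 105 and 476 CPM. The transcription factor gene IRF1 was at 1068 ± 455 CPM and lowest in library 2. The interferon list's median SD of 1.14 log2 compared with 0.32 for random lists of matched expression, above all 10000 of them. The two-sided p from its rank among these random lists was 0.0002, the smallest they can give. It was 0.0032 after Benjamini-Hochberg adjustment over 24 lists. Without library 2 the list still lay at percentile 99.0.

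Most genes of T cells, cytotoxic and NK cells, dendritic cells, and eosinophils and basophils were highest in library 3. Of the T cell genes with at least 1 CPM, 13 of 15 were highest there, such as CD3E (ENSG00000198851) at 14.8, 12.6 and 35.0 CPM. The same held for 9 of 11 cytotoxic and NK cell genes, with GZMB at 4.07, 5.40 and 14.6 CPM. It held for 6 of 8 dendritic cell genes, with CLEC10A at 4.72, 9.07 and 23.5 CPM. It also held for 7 of 10 eosinophil and basophil genes, with MS4A2 at 11.5, 7.14 and 25.9 CPM. GZMB is a member of 2 of these lists, and the dendritic cell gene IRF7 is also in the interferon list. Whether these lists rose independently of one another was not tested. The exceptions, named after their values were seen, were CD4 and TCF7 (T cell), NKG7 (cytotoxic and NK cell), CLEC4C and IRF7 (dendritic cell) and HDC and GATA2 (eosinophil and basophil), all highest in library 1, and NCR1 and RNASE2, highest in library 2. Of 7 B cell genes 2 were highest in library 3 and 4 in library 2, but with the trend on GC content and length removed the median deviation of that list was highest in library 3 (−0.38, 0.09 and 0.41 log2). The largest median deviation in library 3 was that of 4 keratinocyte and epithelial genes (1.18 log2), 2 of which were highest there. In library 3, 10 of 15 neutrophil genes and 12 of 16 immediate early genes were at their lowest, among them CSF3R at 3121, 2705 and 1477 CPM and FOS at 5155, 3226 and 2584 CPM. Mitochondrial ribosomal RNA took 0.183%, 0.440% and 0.727% of reads, most in library 3. Library 3 also carried the strongest relation of expression to GC content: across 10697 genes, which are not independent replicates, the deviation from the mean of the libraries correlated with GC content at r = 0.356, 0.158 and −0.527. In library 2 all 9 immature neutrophil granule genes with at least 1 CPM were highest, with BPI at 12.3, 35.6 and 17.8 CPM and LTF at 11.1, 24.9 and 8.19 CPM.

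In all, 10 of 24 lists had a spread above the limits that hold the central 95% of random lists, where the limits nominally leave 1.2 outside by chance and simulated unshifted lists fell outside in 8.0% of cases, and 0 lay below. The simulated genes varied independently of one another, so that share need not hold for lists of related genes. Raw and adjusted two-sided p from the rank among random lists were 0.0004 and 0.0032 for the T cell and the dendritic cell lists. They were 0.0010 and 0.0060 for monocyte genes and 0.0048 and 0.023 for eosinophil and basophil genes. For cytotoxic and NK cell genes they were 0.0080 and 0.032, and for 4 keratinocyte and epithelial genes 0.013 and 0.045. Immature neutrophil granule genes (0.018 and 0.050), immediate early genes (0.019 and 0.050) and neutrophil genes (0.029 and 0.070) did not pass after adjustment. With the trend on GC content and length removed, the first 2 of these passed (adjusted p 0.017 and 0.025), and 9 lists passed in place of 7. With 1 library left out in turn, the interferon list was the 1 list of the 10 that stayed above the upper limit each time. Without library 3 the T cell list lay at percentile 5.78, cytotoxic and NK cell genes at 28.2, dendritic cell genes at 88.4, eosinophil and basophil genes at 95, keratinocyte genes at 71.7 and immediate early genes at 96.5. Without library 2 the immature neutrophil granule genes lay at 26.5, cytotoxic and NK cell genes at 87.2, eosinophil and basophil genes at 96.9 and immediate early genes at 72.2. Monocyte genes lay at 96.0, 58.2 and 75 and neutrophil genes at 92.1, 71.2 and 87.2 without library 1, 2 and 3. Cytotoxic and NK cell genes also lost the call with a minimum of 5 CPM (70.0) and with no minimum (50.7), immature granule genes with a minimum of 5 CPM (97.0), immediate early genes with no scaling factor (96.9) and neutrophil genes with the trend on GC content and length removed (83.3). These percentiles describe these libraries, since genes are not independent replicates.

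**Figure D3:**
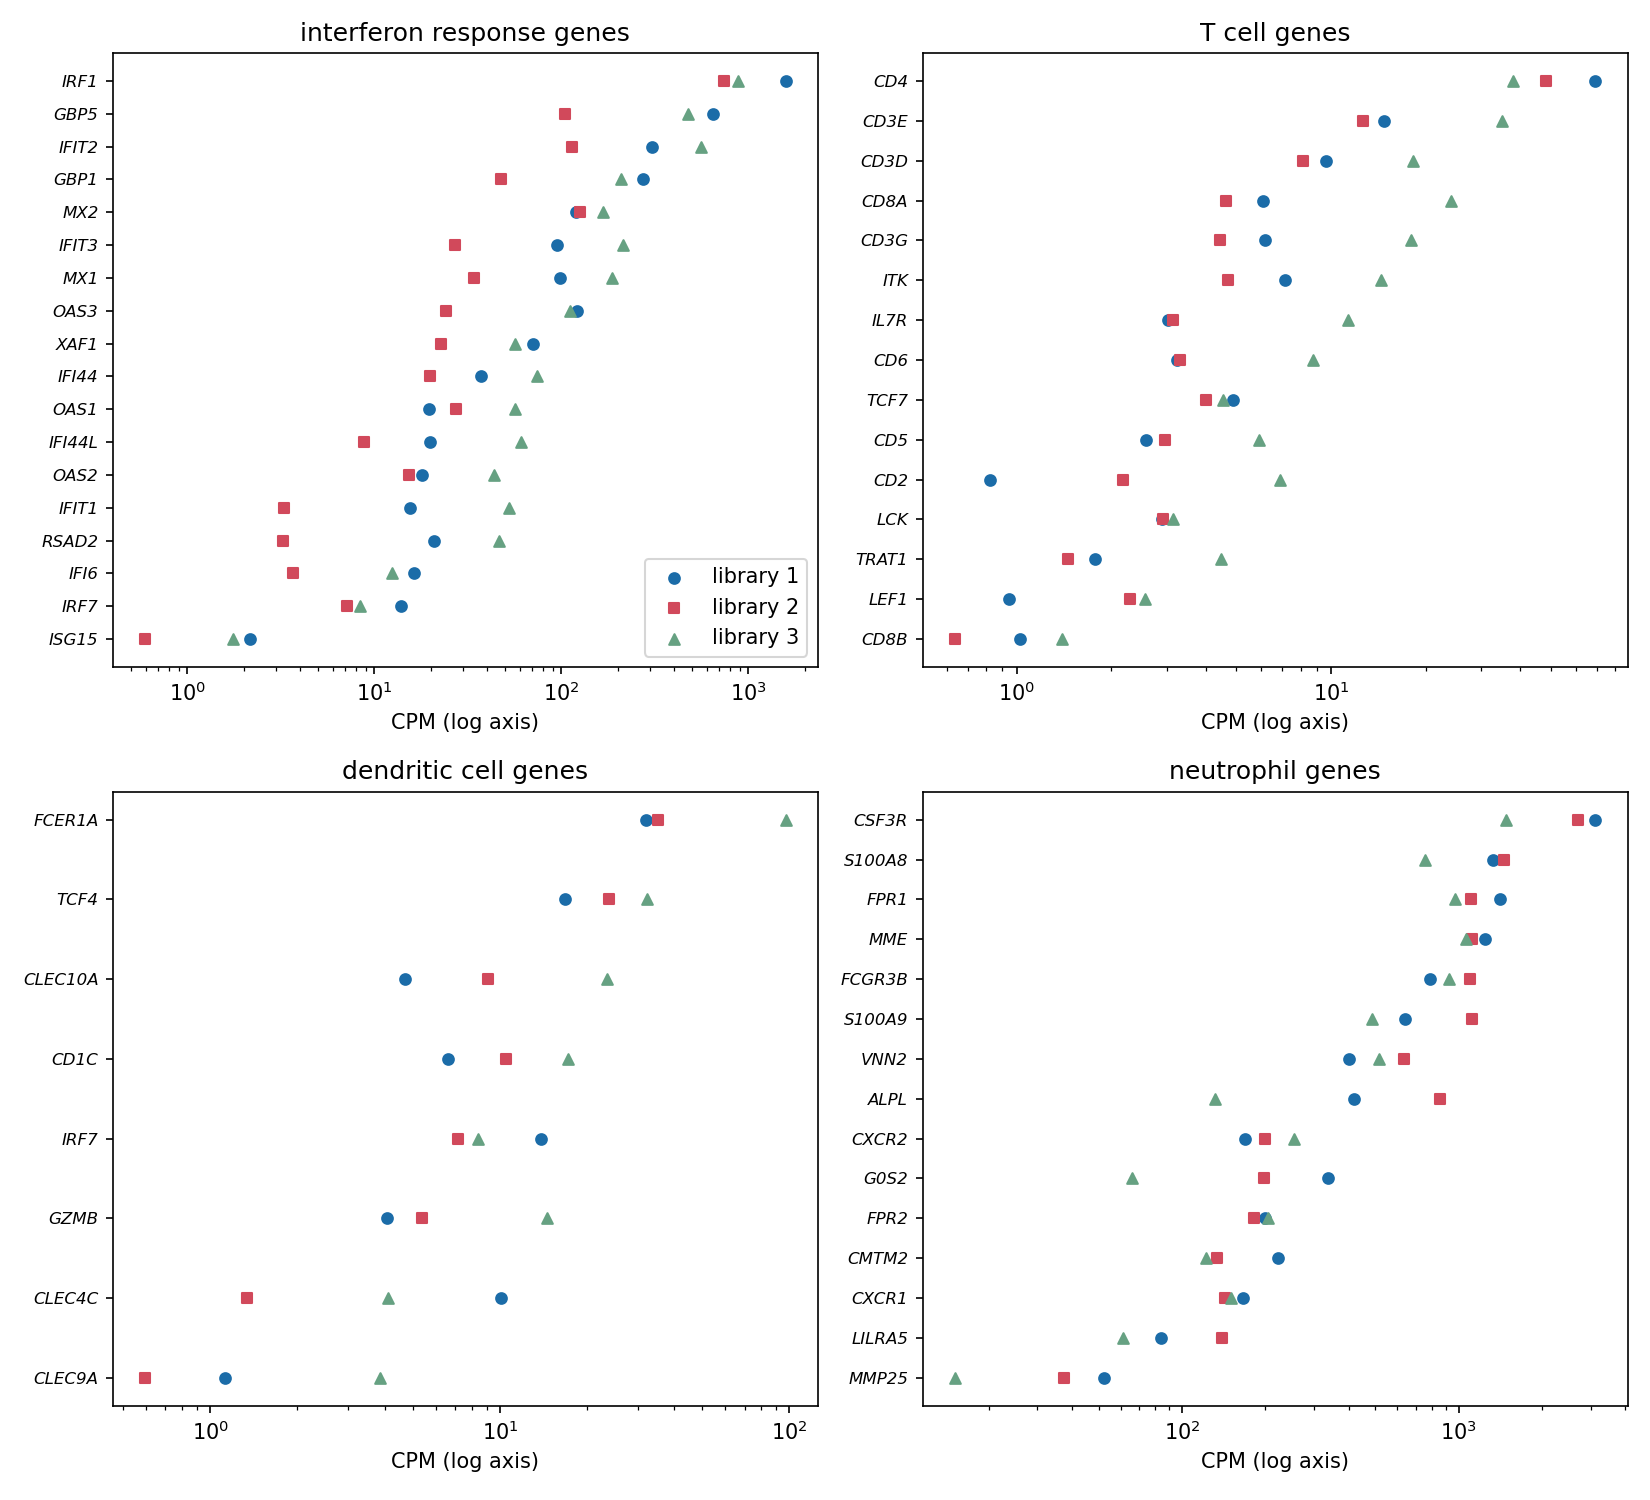
CPM on a log axis of most members with a mean of at least 1 CPM of 4 gene lists in the 3 libraries (symbols). In the full lists, library 2 was lowest for 17 of 19 interferon response genes, and library 3 was highest for 13 of 15 T cell genes and 6 of 8 dendritic cell genes and lowest for 10 of 15 neutrophil genes.

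Single genes with the largest SD between libraries, among those with a mean of at least 10 CPM, included 5 small nucleolar RNA genes. Their SDs of log2 CPM were 3.61 for SNORD3B-2, 2.49 for SNORA46, 2.09 for SNORA71D, 1.97 for SNORA71B and 1.94 for SNORA26. The pseudogene RPS28P7 (4.75) and RGPD2 (4.72) were first, but like SNORD3B-2 and the fetal globin gene HBG2 (2.14) they share sequence with near-identical copies, which makes their counts uncertain. NEBL had an SD of 3.02, the complement regulator gene C4BPA 2.51 and TENM1 2.32. IFIT1 (1.99), the interleukin receptor subunit gene IL18RAP (1.96), RSAD2 (1.96) and the macrophage scavenger receptor gene MARCO (1.72) completed the set of 15.

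Across genes, the libraries resembled one another at Pearson r = 0.962 for libraries 1 and 2, 0.95 for 1 and 3 and 0.965 for 2 and 3 (Spearman rho 0.968, 0.958 and 0.972). Of 12184 genes, 1625, 2739 and 1283 differed by over 2-fold in these pairs. Counts of 11150 of 12952 genes (86.1%) differed between the 3 libraries beyond counting error by a chi-square test with Benjamini-Hochberg adjustment at 0.05, which compares these libraries and not conditions. Between pairs the test called 9140 of 13095, 9775 of 12928 and 8288 of 12955 genes. The biological coefficient of variation by edgeR was 34.6%.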

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

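The alternatives with members under 3 reads set to 3 reads, with members at 0 reads left out, without MITF and 4 background genes, without each library for the named genes, and with the GC and length trend removed were chosen after the data were seen. The number of detected genes (12184 to 15701), the lists at 1 CPM or more in every library (13 to 21 of 27) and the genes that differed beyond counting error (8288 to 11235) stayed within 1.5 times the reported counts under every alternative run. All 110 named genes moved by less than 1 SD under both other scalings, and 2, 0 and 2 of them moved by more without library 1, 2 and 3. Leaving out 1 of 3 libraries can hardly move a mean by 1 SD of those libraries, whatever the values. The leave-one-out counts therefore do not measure stability. The mean CPM of 32 named genes moved by over 1.5 times without some library. Levels of 27 of 28 lists moved by more than 1 SD per kilobase of exon, by the construction of that unit, as did 15 of 27 with members of 10 reads in some library, 8 of 28 without members at 0 reads in every library, 5 of 28 with a prior count of 0.5, 3 of 28 with members under 3 reads set to 3 reads, 2 of 28 under each other scaling, and 4, 2 and 3 of 28 without library 1, 2 and 3. The cancer-testis and background lists had an SD of 0.0, so for them any change counted as moved. For the other lists, leaving out 1 library is bound by the same arithmetic as for single genes. The melanocyte minus background difference was −2.10 log2 with members of 10 reads in some library, because that filter removes background genes at 0 reads. It was 0.00 with members under 3 reads set to 3 reads, because both medians then lie at that floor. The difference was 2.49 with a prior count of 0.5, 0.601 with the mean of each list and 0.402 per kilobase of exon. It was 1.0 to 1.16 with 1 library left out. Of 24 lists, 10 lay above the upper spread limit and 5 to 11 did so with 1 library left out (5 without library 2, 5 without library 3). With 1 library left out the percentile ranged from 5.78 to 100 for T cell genes, from 28.2 to 99.2 for cytotoxic and NK cell genes and from 26.5 to 100 for immature neutrophil granule genes. Cytotoxic and NK cell genes lay at 70.0 with a mean CPM of at least 5 and at 50.7 with no filter, and neutrophil genes at 83.3 with the GC and length trend removed; the cause was not tested. No list crossed a limit with DESeq2 size factors. Strand-column alternatives were not run, since 1 count column per library was used. Depth limits the melanocyte and cancer-testis lists, whose median member had 3 reads or fewer.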

Other observations

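The tests of sequencing depth, of the scaling and of a lower share of neutrophils and monocytes were chosen after the results they concern were seen, as was the description of small RNA; the tests of GC content and length and of reads that align to 2 places were written before their outcome was known.

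Small noncoding RNAs differed between libraries by class. H/ACA small nucleolar RNAs, many but not all of which guide pseudouridylation, took 2.56% of the reads of library 1 (95% Wilson interval 2.55 to 2.56), 0.913% of library 2 (0.910 to 0.915) and 0.925% of library 3 (0.922 to 0.928). Of 45 such genes with at least 10 reads in every library 29 were highest in library 1, 2 in library 2 and 14 in library 3. SNORA73B alone took 2.09%, 0.754% and 0.718%, and the class without it 0.471%, 0.159% and 0.207%. C/D small nucleolar RNAs, many but not all of which guide methylation, took 0.553%, 0.489% and 0.812%, and Cajal body RNAs 0.351%, 0.437% and 0.558%, both highest in library 3. Mitochondrial ribosomal RNA took 0.183%, 0.440% and 0.727%, and messages of ribosomal proteins 2.20%, 3.40% and 3.37%. Many of these RNAs lie in introns of other genes or have close copies, and each share rests on 1 library.

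The interferon response genes differed between libraries, with a range of the list's median deviation of 1.92 log2. Low sequencing depth was argued against, since the library with the lowest level ranked 3 from the fewest reads, that is, it had the most. After removal of the GC and length trend the range was 2.08 log2, which counts against that trend as the whole cause. The lowest range under the other scalings was 1.96 log2. The TMM factors ran from 0.903 to 1.08, so a change among these scalings could not have removed a range of this size. That outcome was fixed before the comparison was made. In library 2, where most interferon genes were lowest, all 9 immature neutrophil granule genes with at least 1 CPM were highest. What stays open is the mix of cells in each library, the donor and the handling of the sample. With 1 group, no biological explanation was tested.

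Most genes of T cells, cytotoxic and NK cells, dendritic cells, and eosinophils and basophils were highest in library 3, where the median deviation of the T cell list was 0.87 log2. After removal of the GC and length trend it was 0.82 log2, although that trend accounted for 29.3% of the variance of deviations in library 3. A lower share of neutrophils and monocytes, if it were the only cause, would raise the markers of every other cell type alike. The T cell list lay 1.04 log2 above the platelet and megakaryocyte list in that library, with quartiles of 0.51 to 1.07 and of −0.74 to 0.06. The erythroid list was at 0.10 log2 there. The platelet list holds F13A1, which monocytes also express, so this comparison cannot exclude a lower share as a part of the cause. The neutrophil and monocyte lists were at −0.34 and −0.29 log2 in library 3. The B cell list had a median deviation of 0.01 log2 in library 3 before and 0.41 log2 after removal of the trend, so whether it follows depends on that correction. The 4 keratinocyte and epithelial genes had a larger deviation there than the T cell list, 1.18 log2 before and 1.32 log2 after the correction. In each of the lists that were mostly highest in library 3, some members were highest in another library. Mitochondrial ribosomal RNA was also highest there. A larger share of some of these cell types, a lower share of neutrophils and monocytes as a part of the cause, the donor and the handling of the sample stay open. With 1 group, none of these could be told apart.

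Several genes had 0 reads in every library although leukocytes express them, among them IL3RA, HSPA1A and HSPA1B. A candidate explanation is that reads aligning to 2 places were not counted. All 18 protein-coding genes of the pseudoautosomal regions, which lie on 2 chromosomes and include IL3RA, had 0 reads in every library (100%), against 23.2% of all protein-coding genes. This is consistent with the loss of such reads; for HSPA1A and HSPA1B, which are near-identical to each other, and for TAP2 it was not tested separately.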
